A study of Homo sapiens with 9 samples.

How the data were processed

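Total RNA was profiled from 9 libraries of the human embryonic stem cell line H9, 3 of undifferentiated cells at day 0, 3 of neuroectoderm and 3 of mesendoderm, both at day 5 of differentiation. Per the labels' protocols, the undifferentiated cells (hESC) were kept on Matrigel in mTeSR1, neuroectoderm was made with the BMP antagonist NOGGIN at 200 nM and the activin and Nodal receptor inhibitor SB431542 at 10 µM, and mesendoderm with BMP4 at 5 ng/ml in mTeSR1. RNA was taken up with a kit that keeps small RNA, treated with DNase, depleted of ribosomal RNA and made into libraries with an Ion Torrent total RNA kit, per the labels' protocols. Samples were grouped by the cell type in their titles. The labels do not state that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

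The values analysed are the RPKM values (read density scaled to transcript length and library size) that the authors computed and deposited in 1 table of 38759 RefSeq transcripts, rounded to 2 decimals. The aligners TopHat, TopHat2 2.0.13 and Bowtie2 and the human build hg19 are named per the submitters' processing notes. The counting tool, its use of strand, its treatment of reads that match several places and the reads that form the denominator of the RPKM values are not given in the sources used here. A gene and an antisense partner, near-identical copies and genes that share exons were therefore read as uncertain. POU5F1, one of the genes fixed for naming, was not analysed here.

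The 21417 gene symbols were each represented by the transcript with the highest mean over the 9 libraries. The 7922 symbols with several transcripts hold 65.2% of the table, and transcripts of 1 gene share reads. The 14473 genes with a mean of at least 0.5 RPKM were tested, of which 742 were small RNA genes by symbol. Values were analysed as log2(RPKM + 1), a scale on which changes of low genes are understated. All 9 libraries entered 1 linear model with group as its term, fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend, and contrasts were called at a Benjamini-Hochberg adjusted p under 0.05. Changes are log2 differences ± SE, and adjusted p-values of genes are limma's with Benjamini-Hochberg adjustment. The low values of each library were whole multiples of the value of 1 read at the transcript's length, within 0.1 of a read for 93.0% to 96.9% of the 129 to 172 values used per library. The steps correspond to 37.0 to 70.5 M reads as the denominator of a library, and 3 reads on a transcript of 1 kb then amount to 0.0425 to 0.0810 RPKM. These floors cover counting error only, and the reads are not independent molecules. Count-based tests were not used, since the values are not counts. In data simulated from the real means and spreads of 14473 genes, a change of 2-fold was called for 81 of 100 genes in neuroectoderm against hESC, 82 in mesendoderm against hESC and 67 in neuroectoderm against mesendoderm. The corresponding values for a 4-fold change were 98, 98 and 92, and 0.0280%, 0.0701% and 0.0981% of unchanged genes were called. The simulation left 14273 genes unchanged and drew each gene independently. In the real data 35.1% to 48.1% of genes were called and libraries shared deviations. The simulated shares are therefore not rates of true or false calls in the real data.

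The 38 gene lists cover pluripotency, neuroectoderm, neural crest and placode, neurons, primitive streak, mesoderm, endoderm, trophoblast, amnion, endothelium and blood, cardiac and smooth muscle, cilium assembly and disassembly, hedgehog, autophagy, lysosome, NRF2 targets and regulators, proteasome, 3 phases or regulators of the cell cycle, targets of 4 signalling pathways, Notch, retinoic acid, HOX, epithelial and mesenchymal genes, glycolysis, oxidative phosphorylation, hypoxia, the unfolded protein response, immediate early genes, ribosomal proteins and histones. They hold 880 entries, of which 855 were matched, 2 of them through another symbol, 9 were second names of members already counted and 16 symbols were not matched. Lists were tested with camera in limma at a preset correlation of 0.01 and again with the correlation estimated per list, with Benjamini-Hochberg adjustment over the 38 lists of a comparison. Members past the threshold were counted after adjustment over all genes and over the list alone. The lists for neural crest, neurons, trophoblast, amnion, endothelium, cardiac muscle, endoderm and pluripotency stand for other cell types the cultures could hold. The genes named are, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 RPKM, leaving out symbols that begin with LOC or with the small RNA prefixes MIR, SNOR, SCARNA, RNU, RN7S, RNY, RNA5 or VTRNA. Added to these are up to 4 members of each list with the largest change past the threshold (or the most abundant member where none passed) and a fixed panel of lineage, NRF2, autophagy, cilium and cell cycle genes. A few genes that this rule selects are not reported here. A gene outside this rule is said to have been chosen after its values were seen. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated.

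The alternatives tried were a pseudocount of 0.1, no filter, a minimum mean of 2 RPKM, median-ratio scaling over genes with at least 1 RPKM in every library, quantile normalization, small RNA symbols left out with the rest rescaled, no trend, robust variances, a replicate block, all transcripts of the table, only the 2 groups compared, a 2-fold minimum, estimated correlations and each library left out in turn. Added after the data were seen were a correction for GC content, a correction for GC content and length, a fit without hESC replicate 2, neuroectoderm replicate 1 and mesendoderm replicate 1 together, and a replicate block in a fit of the 2 lineages alone. Ranges of list members over the scalings cover the fit with all libraries, median-ratio scaling, quantile normalization, small RNA left out, both corrections and the fit without these 3 libraries. GC content and length came from GENCODE v29 transcripts of GRCh38 matched by RefSeq accession for 95.9% of tested genes, and no coordinates are given because that build differs from hg19. Comparisons against the shared hESC libraries were set beside 100 simulations of unchanged groups. Gene families defined by the letters that open a symbol, 168 families of at least 10 tested genes, were tested with Fisher's exact test after the data were seen. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.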

Results

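Transcriptomes of human embryonic stem cells were compared with those of 2 derived lineages. Neuroectoderm is the precursor of the nervous system, and mesendoderm that of mesoderm and endoderm. The series title ties neuroectoderm fate to the cell cycle through primary cilia, autophagy and the transcription factor NRF2. The data are RPKM values of 9 libraries of H9 cells, 3 per group, with denominators of 37.0 to 70.5 M reads. Levels are mean ± SD in RPKM over 3 libraries, and changes log2 differences ± SE of log2(RPKM + 1). List tests are camera with the preset correlation unless stated. Counts are of tested members, such as 12 of 20 trophoblast, 5 of 37 HOX, 5 of 15 endoderm and 9 of 17 neuronal genes. The rest lay under the minimum, which can raise the share that rose. A lost call is given with the library left out, named by group and replicate, and the adjusted p without it.

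Libraries separated by cell type. Components 1 and 2 held 52.5% and 29.9% of the variance, and Pearson correlations across genes were 0.933 to 0.992 within groups, genes not being independent replicates. Component 3, with 12.3%, set hESC replicate 2, neuroectoderm replicate 1 and mesendoderm replicate 1 apart from the others of their groups. In hESC replicate 2 and neuroectoderm replicate 1 the deviations of genes from their group means fell with GC content across genes, with Spearman correlations of -0.696 and -0.652, and in mesendoderm replicate 1 with -0.348, while the other 6 libraries had 0.241 to 0.679. Genes other than small RNA took 57.3% of the reads of neuroectoderm replicate 1 and 61.9% of those of hESC replicate 2, against 68.0% to 71.3% elsewhere. Small RNA genes took 7.05% in neuroectoderm replicate 1 and 3.42% to 4.97% in the other libraries. Replicates of a group differed by more than sampling noise, with chi-square values per gene of 16.0 to 263.9, so each library was counted once.

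**Figure D1:**
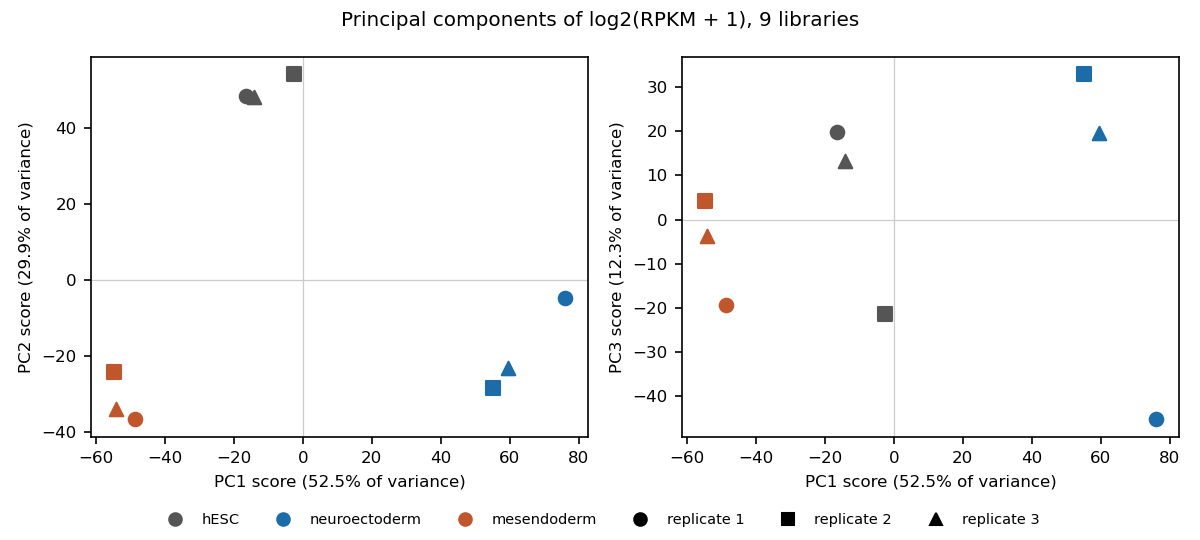
Scores of the 9 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(RPKM + 1), with colours for the groups and symbols for the replicates. Components 1 and 2 part the 3 groups, and component 3 places neuroectoderm replicate 1 at -45.26 and neuroectoderm replicate 2 at 32.89.

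Neuroectoderm was compared with hESC to describe the neural path. The cells gained transcripts of neural plate regulators and lost those of pluripotency and of epithelial junctions. PAX6, a master regulator of the neural plate and eye, went from 0.093 ± 0.021 to 28.4 ± 7.2 RPKM (4.71 ± 0.17, adjusted p = 1.47e-07), and PAX3, a regulator of the dorsal neural tube and neural crest, from 0.063 ± 0.051 to 68.1 ± 17.8. The head organiser gene OTX2 rose from 36.7 ± 3.37 to 176 ± 4.07. NANOG fell from 22.0 ± 1.28 to 0.127 ± 0.05 (-4.35 ± 0.24, adjusted p = 1.67e-06), and E-cadherin (CDH1) from 54.7 ± 4.45 to 0.270 ± 0.121. SOX2, shared by pluripotent and neural cells, did not pass the test (63.3 ± 10.5 against 42.6 ± 8.19 RPKM, -0.57 ± 0.35, adjusted p = 0.220). Of 14473 genes 3165 were higher and 3228 lower in neuroectoderm (44.2%), 880 and 1183 of them by at least 2-fold. The groups did not overlap for 51.9% of genes, where chance gives 10%.

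On the log2(RPKM + 1) scale, which understates changes of low genes, the largest rise was that of IGFBP5 (6.75 ± 0.16). This gene, which codes for a secreted protein that binds insulin-like growth factors, went from 0.670 ± 0.159 to 179 ± 4.55 RPKM. WLS, which carries WNT proteins to the cell surface, rose by 6.50 to 198 ± 54.7, and PRTG, a cell surface protein of early neural tissue, by 6.003 to 207 ± 32.3. The transcription factor ZFHX4 (5.09 ± 0.07), the eye field gene MAB21L2 (5.38 ± 0.11), GREB1L (5.94 ± 0.31), the inducible nitric oxide synthase NOS2 (5.17 ± 0.33), the WNT-inhibiting surface protein TPBG (5.02 ± 0.18) and smooth muscle actin (ACTA2, 5.45 ± 0.24) completed the 10 largest rises with PAX3. Among the largest falls were the stem cell transcript LINC00678 (-6.24 ± 0.28), the RNA-binding protein L1TD1 (-6.03 ± 0.19), the Nodal co-receptor TDGF1 (-5.76 ± 0.25), the epithelial splicing factor ESRP1 (-5.32 ± 0.12) and AP1M2, part of the sorting machinery of epithelial cells (-5.15 ± 0.18). The kinase LCK (-4.86), the tryptophan-degrading enzyme IDO1 (-4.84), the receptor kinase EPHA1 (-4.71) and LECT1 (-4.67) fell as well.

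**Figure D2:**
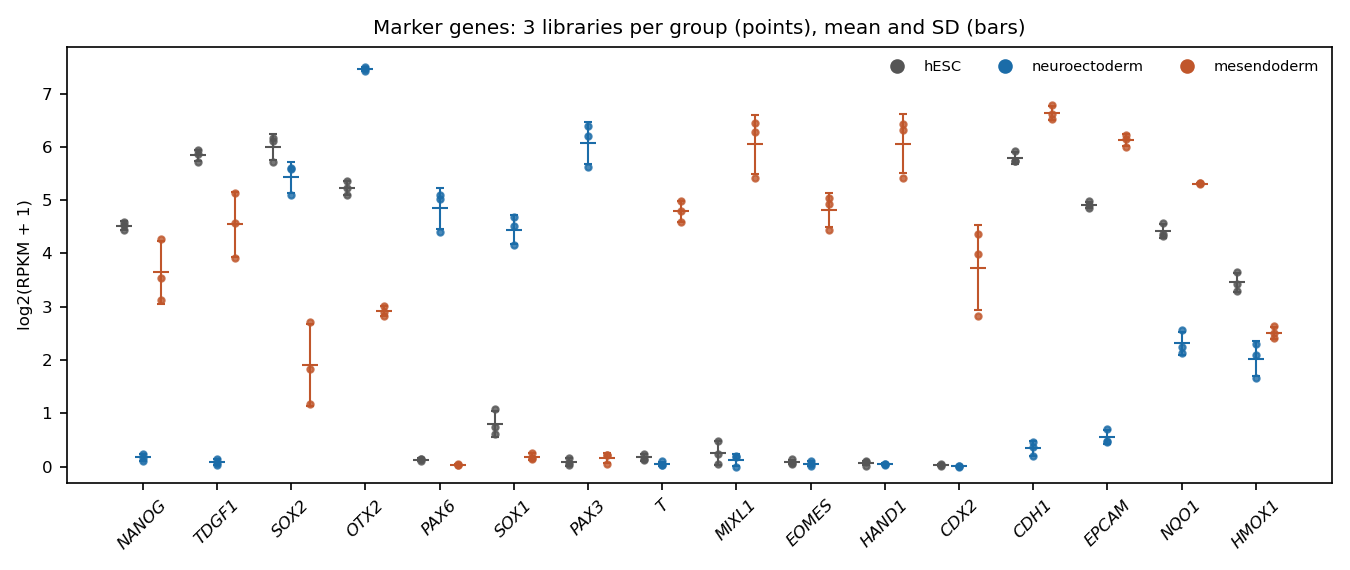
Levels of 16 marker genes as log2(RPKM + 1) in hESC, neuroectoderm and mesendoderm, with points for the 3 libraries of a group and bars for their mean and SD. NQO1 averaged 20.5 RPKM in hESC and 38.7 in mesendoderm.

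Of 26 tested pluripotency genes 21 fell and 0 rose (21 and 1 adjusted over the list alone, median -1.99). The pluripotency list had adjusted p = 2.46e-10, and 0.340 with an estimated correlation. The zinc finger factor ZSCAN10 fell by 4.30 on the log2 scale. Of 30 tested neuroectoderm genes 23 rose and 2 fell (23 and 2 adjusted over the list alone, median 2.22), led by the nuclear receptors NR2F2 (4.99 ± 0.18) and NR2F1 (4.77 ± 0.21) and by ZBTB16 (4.72 ± 0.14). The neuroectoderm list had adjusted p = 2.12e-10, and 0.0971 with an estimated correlation. SOX1, a marker of the committed neural plate, went from 0.767 ± 0.307 to 21.1 ± 3.99 RPKM. Of 15 epithelial genes 13 fell and 0 rose (13 and 0 adjusted over the list alone, median -2.67), among them the adhesion molecule EPCAM (-4.36 ± 0.11) and the tight junction gene CLDN6 (-3.96 ± 0.21). The epithelial list had adjusted p = 1.15e-09, and 0.0856 with an estimated correlation. Of 13 mesenchymal genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, list adjusted p = 0.1, called with small RNA left out (0.0439) and without mesendoderm 2 (0.0231)), with rises of the E-cadherin repressors ZEB2 (3.46 ± 0.27) and ZEB1 (2.01 ± 0.15), of CDH11 (2.91 ± 0.44) and of vimentin (VIM, 1.79 ± 0.48).

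Cilium genes rose together in neuroectoderm. Of 82 tested cilium assembly genes 51 rose and 2 fell (53 and 2 adjusted over the list alone), with a median of 0.51. The cilium assembly list had adjusted p = 4.24e-08, and 0.0856 with an estimated correlation. The intraflagellar transport genes IFT140 (6.51 ± 0.692 to 18.7 ± 3.45 RPKM, 1.38 ± 0.14) and IFT81 (1.28 ± 0.13), the ciliary receptor gene GPR161 (1.17 ± 0.10) and the dynein-2 subunit gene DYNC2LI1 (1.13 ± 0.11) changed most. IFT88 (0.43 ± 0.18, adjusted p = 0.0773, past the threshold with a replicate block (0.0343) and without mesendoderm 1 (0.0395)) and the kinesin-2 subunit KIF3A (0.45 ± 0.19, adjusted p = 0.0812, past the threshold in 3 settings at 0.0252 to 0.044) did not pass the test. With small RNA left out and the rest rescaled, 30 members rose and the list was still called (adjusted p = 1.65e-07, against 1.50e-10 to 1.17e-06 over all alternatives that keep the preset correlation). Without the 3 libraries that stood apart 56 rose and 2 fell. Of 13 cilium disassembly genes 7 rose and 0 fell (7 and 1 adjusted over the list alone), among them NEDD9, a scaffold that activates Aurora A (2.20 ± 0.13), CEP97 (0.90 ± 0.16), which caps centrioles, KIF24 (0.87 ± 0.09) and NDE1 (0.86 ± 0.14). The cilium disassembly list had adjusted p = 0.0315, and 0.658 with an estimated correlation. Of 10 hedgehog pathway genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.999). The hedgehog pathway list had adjusted p = 0.00558, and 0.808 with an estimated correlation. The co-receptors BOC (4.53 ± 0.23), GAS1 (3.43 ± 0.21) and CDON (3.07 ± 0.10) and the transcription factor GLI3 (5.23 ± 0.380 to 61.6 ± 4.75 RPKM) rose.

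NRF2 target genes were lower in neuroectoderm. NQO1, a quinone reductase, fell from 20.5 ± 1.99 to 4 ± 0.781 RPKM (-2.11 ± 0.13, adjusted p = 2.76e-06), and heme oxygenase 1 (HMOX1) from 10.0 ± 1.35 to 3.12 ± 0.899 (-1.44 ± 0.17, adjusted p = 1.51e-04). Of 33 tested targets 15 fell and 4 rose (15 and 4 adjusted over the list alone, median -0.59), including the epoxide hydrolase EPHX1 (-1.87 ± 0.16), the carbonyl reductase CBR1 (-1.70 ± 0.38) and transketolase (TKT, -1.57 ± 0.37). The NRF2 target list had adjusted p = 0.0168, and 0.808 with an estimated correlation. NFE2L2, which codes for NRF2, was at 7.25 ± 0.626 RPKM in hESC and 8.94 ± 1.56 in neuroectoderm (0.26 ± 0.13, adjusted p = 0.127, past the threshold without the 3 libraries that stood apart (0.00675) and without neuroectoderm 1 (0.0153)), and its inhibitor KEAP1 at 26.1 ± 4.74 and 21.5 ± 8.38 (-0.34 ± 0.29, adjusted p = 0.372). Of 11 NRF2 regulators 3 rose and 3 fell (3 and 3 adjusted over the list alone, list adjusted p = 0.994), and over the scalings 0 to 5 rose and 1 to 3 fell. The repressor BACH1 rose (0.50 ± 0.13, call lost in 1 setting), and the small MAF partners MAFK (-1.01 ± 0.13), MAFF (-0.48 ± 0.13, call lost without hESC 3 (0.055) and in 3 other settings) and MAFG (-0.44 ± 0.11, call lost in 2 settings) fell.

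Autophagy genes moved in both directions, with 8 of 43 up and 5 down (8 and 5 adjusted over the list alone, median 0.10, adjusted p = 0.520). The initiating kinase ULK2 (1.33 ± 0.15) and the receptor CALCOCO2 (0.82 ± 0.11) rose. The cargo receptor SQSTM1, itself an NRF2 target, fell (28.5 ± 2.72 to 14.8 ± 1.28 RPKM) together with MAP1LC3C (-0.97 ± 0.12), while ULK1 did not pass the test (-0.07 ± 0.17, adjusted p = 0.768). Under the rescaling without small RNA 4 rose and 6 fell with a median of -0.03, and without the 3 libraries that stood apart 16 rose and 8 fell. Lysosome genes numbered 5 up and 4 down of 29 (4 and 3 adjusted over the list alone, list adjusted p = 0.968), with a fall of the regulator TFE3 (-1.45 ± 0.11) and rises of cathepsin B (CTSB, 1.26 ± 0.23), SCARB2 (0.84 ± 0.11) and GAA (0.75 ± 0.15). Over the scalings 4 to 10 rose and 3 to 4 fell in the lysosome list. Of 33 proteasome genes 15 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.54), among them PSMA3 (-1.15 ± 0.18), the assembly factor POMP (-1.07 ± 0.14), PSMA5 (-1.06 ± 0.12) and ADRM1 (-0.90 ± 0.22). The proteasome list had adjusted p = 5.38e-04, and 0.890 with an estimated correlation. Without neuroectoderm replicate 1 the proteasome median was -0.34, and without hESC replicate 3 9 fell.

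Among cell cycle regulators CDKN1B, the inhibitor p27, rose from 10.2 ± 0.772 to 22.5 ± 1.51 RPKM (1.06 ± 0.10), while cyclin D1 (CCND1) did not pass the test (0.33 ± 0.16, adjusted p = 0.124, past the threshold in 5 settings at 0.00373 to 0.0438). CDKN1A rose (0.53 ± 0.15, adjusted p = 0.0204), and CCND3 (-0.74 ± 0.24, adjusted p = 0.0318) fell. CCND3 had its call lost without hESC 1, 2 or 3 (0.0638 to 0.0878) and in 1 other setting. CDKN1A had its call lost without hESC 3 or neuroectoderm 2 or 3 (0.0631 to 0.0763) and in 1 other setting. In all 4 of 14 G1 regulators rose and 2 fell (4 and 2 adjusted over the list alone, list adjusted p = 0.256), and over the scalings 1 to 8 rose and 2 to 3 fell. Of 21 G1/S genes 2 rose and 6 fell (3 and 8 adjusted over the list alone, list adjusted p = 0.250). Thymidylate synthase (TYMS, 1.13 ± 0.25) rose and the ribonucleotide reductase subunit RRM2 (-0.96 ± 0.19) and the replication licensing gene CDC6 (-0.78 ± 0.11) fell. Of 22 G2/M genes 2 rose and 4 fell (1 and 3 adjusted over the list alone, list adjusted p = 0.920), a balance that turned with the scaling (0 to 6 rose and 2 to 7 fell). The spindle checkpoint kinase BUB1 fell (-0.99 ± 0.13) with HMMR (-0.60) and BUB1B (-0.45, call lost in 1 setting), and NUSAP1 rose (0.54, call lost without hESC 2 or 3 or neuroectoderm 2 or 3 (0.0631 to 0.0852) and in 2 other settings). Of 32 replication-dependent histones, whose near-identical copies can share reads, 2 rose and 2 fell (1 and 2 adjusted over the list alone, list adjusted p = 0.549).

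WNT target genes rose in neuroectoderm and FGF targets fell. Of 11 WNT targets 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.66), including LEF1 (0.273 ± 0.021 to 16.8 ± 1.26 RPKM), APCDD1 (3.796 ± 0.23), SP5 (3.76 ± 0.25) and AXIN2 (7.82 ± 0.626 to 73.5 ± 22.7 RPKM). The WNT target list had adjusted p = 6.41e-05, and 0.245 with an estimated correlation. Of 10 FGF and ERK targets 7 fell and 1 rose (7 and 1 adjusted over the list alone, median -1.03), with ETV4 (-4.37 ± 0.14), the feedback inhibitors SPRY4 (-3.05 ± 0.17) and SPRY1 (-1.40 ± 0.18) and the ERK phosphatase DUSP6 (-2.32 ± 0.17) lower. The FGF and ERK target list had adjusted p = 0.00896, and 0.340 with an estimated correlation. Notch pathway genes rose (6 of 13 up, 1 down; 6 and 1 adjusted over the list alone), among them HES4 (3.06), LFNG (2.44) and the ligands JAG1 (2.93) and DLL1 (2.62). The Notch pathway list had adjusted p = 0.0236, and 0.890 with an estimated correlation. Of 12 BMP targets 7 rose and 2 fell (7 and 2 adjusted over the list alone, list adjusted p = 0.134, called with no filter (0.0425) and with small RNA left out (0.00877)), with MSX1 (4.60 ± 0.43) and BMP4 (2.86 ± 0.32) up and the inhibitory SMAD7 down (-2.16 ± 0.12). Of 10 Nodal and activin targets 6 fell and 1 rose (6 and 1 adjusted over the list alone, list adjusted p = 0.0523, called in 10 settings at 0.00612 to 0.0481), with SKIL (-2.90 ± 0.17), GDF3 (-1.60 ± 0.44, call lost without hESC 1 (0.0586)) and LEFTY1 (-1.48 ± 0.23) lower beside TDGF1. In the retinoic acid list 2 of 7 rose and 2 fell (2 and 2 adjusted over the list alone, list adjusted p = 0.920), with the retinal reductase DHRS3 lower (-3.03 ± 0.17) and CRABP2 higher (1.48 ± 0.27). Of 5 tested HOX genes HOXD1 fell (-1.04 ± 0.32, adjusted p = 0.0286, call lost without hESC 1 or 2 or neuroectoderm 2 or 3 (0.0837 to 0.0954) and in 4 other settings, 0 adjusted over the list alone, list adjusted p = 0.829).

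Glycolysis genes were lower in neuroectoderm, 9 of 18 down and 0 up (9 and 0 adjusted over the list alone, median -0.77), with falls of the aldolases ALDOC (-2.95 ± 0.15) and ALDOA (-1.23 ± 0.26), hexokinase 2 (HK2, -2.15 ± 0.12) and lactate dehydrogenase A (LDHA, -1.099 ± 0.16). The glycolysis list had adjusted p = 0.0208, and 0.890 with an estimated correlation. Of 44 oxidative phosphorylation genes 6 fell and 0 rose (6 and 0 adjusted over the list alone), led by ATP5G1 (-1.57 ± 0.38) and COX8A (-1.25 ± 0.29). Of these genes 20 fell without the 3 libraries that stood apart, 12 without hESC replicate 2 and 10 without neuroectoderm replicate 2. The oxidative phosphorylation list had adjusted p = 0.0208, and 0.964 with an estimated correlation. Without neuroectoderm replicate 1 neither list was called (0.133 for glycolysis and 0.252 for oxidative phosphorylation), and without hESC replicate 1 the latter had 0.107. Over all alternatives that keep the preset correlation the lists had 0.00483 to 0.133 and 0.00156 to 0.252. In the hypoxia list 5 of 11 rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.829), with adrenomedullin (ADM, -3.95 ± 0.16) and PDK1 (-1.89 ± 0.14) lower and the oxygen sensor EGLN3 higher (1.39 ± 0.18). The unfolded protein and ATF4 list had 5 rises and 2 falls among 15 (5 and 2 adjusted over the list alone, list adjusted p = 0.549), with DDIT4 up (1.76 ± 0.33) and the chaperone HSPA5 down (-1.40 ± 0.17). Of 9 immediate early and heat shock genes 3 rose and 1 fell (3 and 3 adjusted over the list alone, list adjusted p = 0.797), with ATF3 (2.05 ± 0.12) and EGR1 (1.69 ± 0.16) higher. None of 42 ribosomal protein genes passed the limma test in any of the 3 comparisons, and 2, 1 and 2 had an unadjusted p under 0.05 (over the scalings 0 to 1 rose and 0 to 3 fell in neuroectoderm and 0 to 2 rose and 0 to 1 fell in mesendoderm against hESC). The list had adjusted p = 0.549 in neuroectoderm and 0.255 in mesendoderm against hESC, the latter called without hESC 1 (0.0265). RPLP0, the most abundant, was at 1019 ± 175 RPKM in hESC and 1006 ± 491 in neuroectoderm.

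Markers of other cell types were mixed. Of 16 neural crest and placode genes 8 rose and 3 fell (8 and 3 adjusted over the list alone, list adjusted p = 0.197, called with no filter (0.0466) and with small RNA left out (0.0159)), with PAX3 and MSX1 up and the placode gene FOXI3 (-2.29 ± 0.08) and ETS1 (-2.13 ± 0.11) down. Neuronal genes numbered 4 up and 4 down of 9 (5 and 4 adjusted over the list alone, list adjusted p = 0.829). TUBB3 fell (-1.76 ± 0.58, adjusted p = 0.0363, call lost without hESC 1 or 3 or mesendoderm 1, 2 or 3 (0.0504 to 0.114) and in 2 other settings). The primitive streak genes MIXL1, EOMES and T (brachyury) averaged 0.09 RPKM or less in neuroectoderm, while 5 of 20 list members rose and 1 fell (4 and 0 adjusted over the list alone, list adjusted p = 0.256, called with small RNA left out (0.0422)), among them SP5, DKK1 (2.10 ± 0.12) and WNT3A (1.75 ± 0.27). In the mesoderm list 4 of 17 rose and 3 fell (4 and 3 adjusted over the list alone, list adjusted p = 0.573), with MEIS1 higher (2.70 ± 0.22) and KDR lower (-2.33 ± 0.11). In the endoderm list the chemokine receptor CXCR4 rose (3.13 ± 0.27) and FOXA3 fell (-1.18 ± 0.34, call lost without hESC 1 or 3 (0.0595 to 0.075)) among 5 (list adjusted p = 0.968). Of 12 trophoblast genes 2 rose and 3 fell (2 and 3 adjusted over the list alone, list adjusted p = 0.744), with KRT7 lower (-2.46 ± 0.16) and TFAP2C higher (1.57 ± 0.16). Of 13 amnion genes 4 rose and 3 fell (4 and 3 adjusted over the list alone, list adjusted p = 0.702). Of 5 endothelium and blood genes 2 rose and 1 fell (2 and 1 adjusted over the list alone, list adjusted p = 0.573), with VWF (1.33 ± 0.12) and TEK (0.73 ± 0.11) higher. Of 8 cardiac and smooth muscle genes 5 rose and 0 fell (5 and 0 adjusted over the list alone), namely smooth muscle genes ACTA2 and TAGLN (61.2 ± 7.56 to 321 ± 17.7 RPKM) with MYL4 (2.16 ± 0.36) and ACTC1 (1.41 ± 0.19) among them. The cardiac and smooth muscle list had adjusted p = 0.0236, and 0.658 with an estimated correlation. With small RNA left out and the rest rescaled, 2259 genes were higher and 3986 lower in neuroectoderm, and the median of all genes moved from -0.024 to -0.149. That fit tested 16040 genes in place of 14473, so small changes depend on the scaling and the genes kept, which are not separated here.

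**Figure D3:**
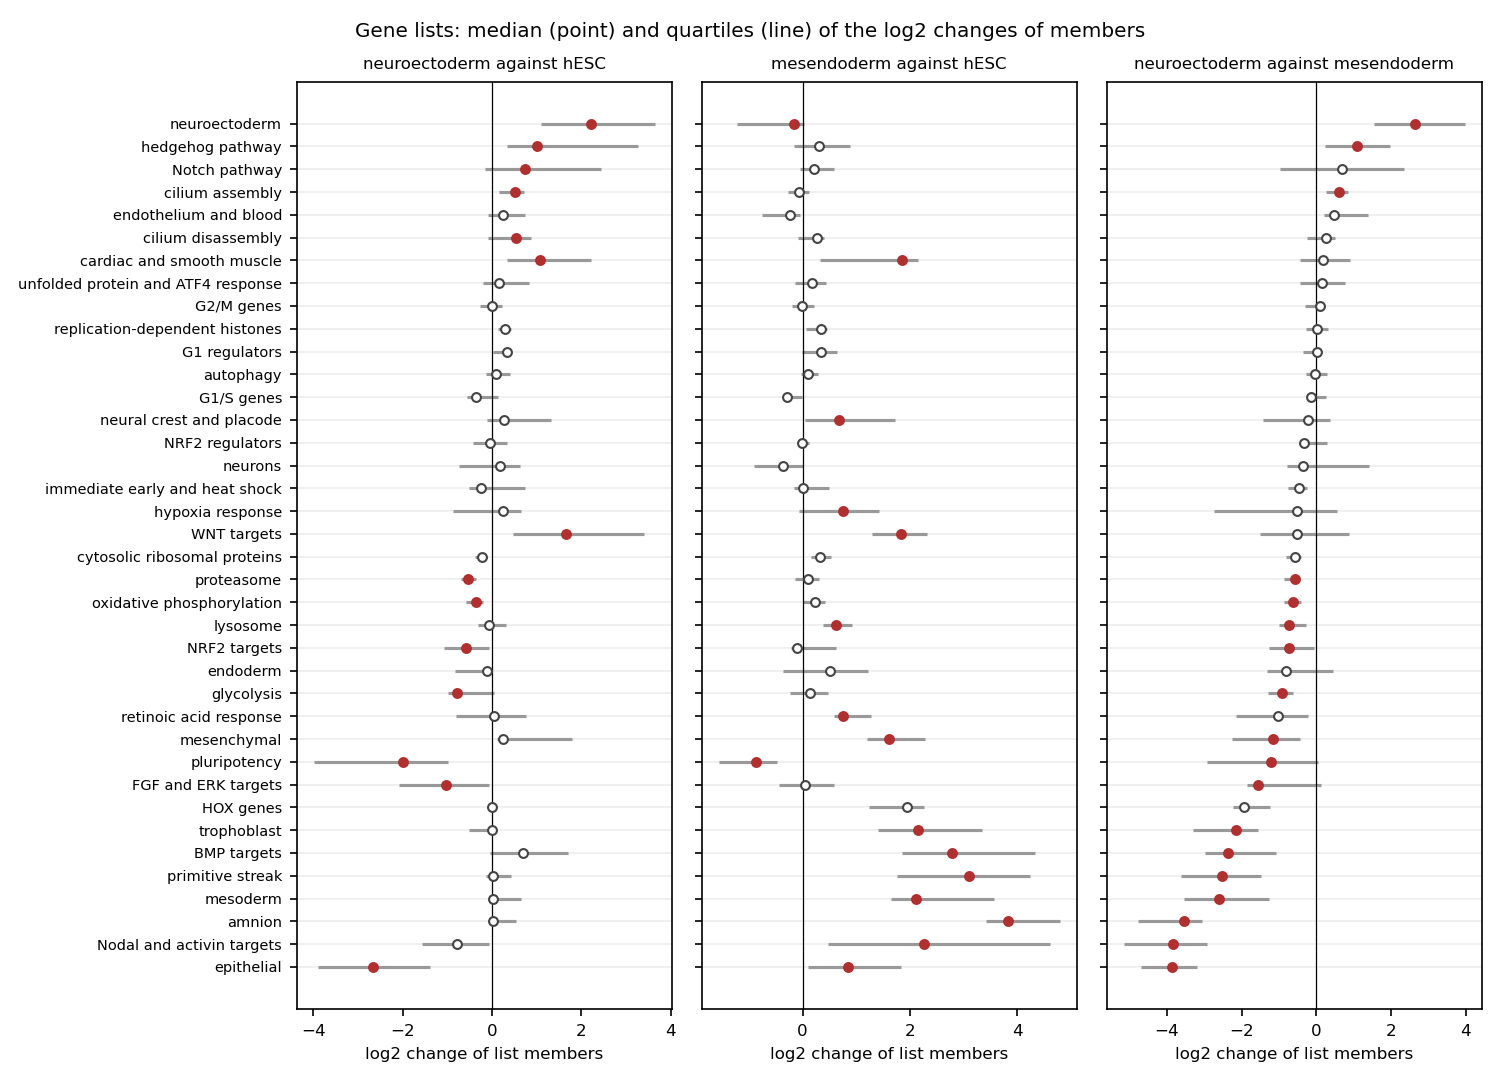
Median (point) and quartiles (line) of the log2 changes of the members of 38 gene lists in the 3 comparisons, with filled points for lists past the threshold of the preset-correlation test. Called lists number 14, 16 and 18 from left to right, and 0, 0 and 3 with an estimated correlation.

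Mesendoderm was compared with hESC to describe the BMP4 path. Primitive streak and mesoderm regulators that were near 0 in hESC were induced. T (brachyury), the defining transcription factor of the streak, went from 0.127 ± 0.047 to 26.9 ± 3.84 RPKM (4.62 ± 0.11, adjusted p = 2.81e-08). MIXL1 went from 0.203 ± 0.186 to 68.3 ± 23.5, EOMES from 0.063 ± 0.032 to 27.4 ± 5.90 and HAND1, a factor of lateral mesoderm and extraembryonic tissue, from 0.047 ± 0.032 to 68.7 ± 23.5. SOX2 fell from 63.3 ± 10.5 to 3.11 ± 2.20 (-4.09 ± 0.35, adjusted p = 2.85e-05), whereas NANOG fell less, from 22.0 ± 1.28 to 12.2 ± 5.56 (-0.88 ± 0.24, adjusted p = 0.0213, call lost without hESC 1 or 3 or mesendoderm 1 or 3 (0.0544 to 0.0742)). In all 2457 genes were higher and 2620 lower (35.1%), 975 and 683 of them by at least 2-fold. The groups did not overlap for 54.7% of genes, where chance gives 10%.

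On the log2(RPKM + 1) scale the largest rises were those of WLS (6.43 ± 0.22), the apelin receptor APLNR (6.39 ± 0.43), fibronectin (FN1, 14.1 ± 0.436 to 1123 ± 64.7 RPKM, 6.21 ± 0.14), the neuropeptide gene NTS (6.12 ± 0.15) and HAND1. Next came the secreted phospholipase PLA2G2A (5.83 ± 0.11), MIXL1, the prostaglandin-degrading enzyme HPGD (5.66 ± 0.08), the hypoxia factor EPAS1 (5.56 ± 0.19) and BMP4 itself (1.02 ± 0.356 to 99.3 ± 45.7 RPKM). The largest falls were those of HES3 (-4.69 ± 0.17), IDO1 (-4.63 ± 0.08), the neuronal pentraxin NPTX1 (-4.60 ± 0.11), SNAR-G2, a small noncoding RNA with near-identical copies (-4.20 ± 0.44), and SOX2. Others were the WNT antagonist SFRP1 (195 ± 6.25 to 11.5 ± 2.33 RPKM), chromogranin A (CHGA, -3.78 ± 0.18), CUZD1 (-3.77 ± 0.13), GPR176 (-3.73 ± 0.14) and the forebrain factor FEZF1 (-3.70 ± 0.12).

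All 20 tested primitive streak genes rose (20 and 0 adjusted over the list alone, median 3.11), with the secreted antagonist CER1 (5.33 ± 0.17) and SP5 (5.24 ± 0.25) among the largest. The primitive streak list had adjusted p = 1.10e-15, and 0.0778 with an estimated correlation. Of 17 mesoderm genes 15 rose and 0 fell (15 and 1 adjusted over the list alone, median 2.12), TBX3 by 4.80 ± 0.27. The mesoderm list had adjusted p = 9.28e-10, and 0.280 with an estimated correlation. Endoderm markers were few, with GATA6 (4.82 ± 1.98 RPKM, 2.35 ± 0.23) and SOX7 (1.21 ± 0.15) up and APOA1 (-1.27 ± 0.33, adjusted p = 0.0173, call lost without hESC 1 or 2 or mesendoderm 2 (0.0516 to 0.0654) and in 2 other settings) down among 5 (2 and 1 adjusted over the list alone, list adjusted p = 0.327). SOX17, the definitive endoderm factor, lay under the expression minimum, at 0.28, 0.06 and 0.32 RPKM in the mesendoderm libraries. All 13 amnion genes rose (13 and 0 adjusted over the list alone, median 3.83), and of 12 trophoblast genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, median 2.16). The amnion list had adjusted p = 3.45e-14, and 0.141 with an estimated correlation. The trophoblast list had adjusted p = 2.78e-08, and 0.120 with an estimated correlation. TFAP2A (3.83 ± 0.12), GATA3 (3.42 ± 0.11), TFAP2C (3.33 ± 0.16) and CDX2 (0.02 ± 0.01 to 13.6 ± 6.89 RPKM, 3.70 ± 0.32), factors of trophoblast and other BMP-driven tissues, and MSX2 (5.11 ± 0.29) were among them. The amnion and trophoblast lists share CDX2, KRT7 and TFAP2A, and amnion shares HAND1, TBX3, BMP4 and ISL1 with mesoderm.

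Pluripotency genes fell in mesendoderm, 17 of 26 down and 2 up (20 and 2 adjusted over the list alone, median -0.86), with USP44 (-3.54 ± 0.26) and PRDM14 (-2.84 ± 0.22) lower and the signal NODAL higher (1.12 ± 0.051 to 44.7 ± 25.8 RPKM). The pluripotency list had adjusted p = 7.21e-06, and 0.451 with an estimated correlation. The libraries of mesendoderm differed here, with NANOG at 7.68, 18.4 and 10.6 RPKM, SOX2 at 1.25, 5.54 and 2.55, and CDX2 at 19.7, 6.13 and 14.9 in replicates 1 to 3. Of 30 neuroectoderm genes 11 fell and 3 rose (11 and 3 adjusted over the list alone), with OTX2 (-2.32 ± 0.11), POU3F1 (-2.03 ± 0.23), ZIC5 (-1.96 ± 0.12) and SOX1 (-0.62 ± 0.16, adjusted p = 0.016, call lost without hESC 1 or mesendoderm 1 (0.0524 to 0.0561)) lower and PAX6 near 0 in both groups. The neuroectoderm list had adjusted p = 0.0283, and 0.470 with an estimated correlation. The call was lost with quantile normalization (0.0888) and without mesendoderm replicate 2 (0.0761), of 0.0134 to 0.0888 over these alternatives. Of 16 neural crest and placode genes 10 rose and 1 fell (11 and 2 adjusted over the list alone), including MSX1 (4.29 ± 0.43), DLX5 (3.42 ± 0.10), DLX6 (1.99 ± 0.11) and SNAI2 (2.28 ± 0.46), which also act in mesoderm and surface ectoderm. The neural crest and placode list had adjusted p = 4.20e-04, and 0.280 with an estimated correlation. Among 9 neuronal genes 2 rose and 4 fell (2 and 5 adjusted over the list alone, list adjusted p = 0.378), with GAD1, the enzyme that makes GABA, up to 22.1 ± 3.24 RPKM and DCX (-0.90 ± 0.08) down.

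All 12 BMP targets (12 and 0 adjusted over the list alone, median 2.79) and all 11 WNT targets (11 and 0 adjusted over the list alone, median 1.83) rose. The BMP target list had adjusted p = 3.41e-10, and 0.141 with an estimated correlation. The WNT target list had adjusted p = 8.98e-08, and 0.120 with an estimated correlation. The BMP pseudoreceptor BAMBI rose from 4.69 ± 0.252 to 129 ± 33.5 RPKM, LEF1 by 2.91 ± 0.28, DKK1 by 2.62 ± 0.12 and NOTUM by 2.02 ± 0.20. Of 10 Nodal and activin targets 7 rose and 2 fell (7 and 2 adjusted over the list alone, median 2.26). The Nodal and activin target list had adjusted p = 2.83e-04, and 0.470 with an estimated correlation. FGF and ERK targets were mixed, 3 up and 3 down of 10 (4 and 3 adjusted over the list alone, list adjusted p = 0.909; SPRY2 1.499 ± 0.15, ETV1 -1.27 ± 0.10). Of 13 Notch genes 5 rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.378; HES1 1.59 ± 0.23, DLL3 2.23 ± 0.50). In the retinoic acid list 4 of 7 rose and 0 fell (4 and 1 adjusted over the list alone), including the retinoic acid hydroxylase CYP26A1 (1.30 ± 0.19). The retinoic acid response list had adjusted p = 0.0484, and 0.480 with an estimated correlation. The call was lost in 11 further settings, among them without hESC 2 (0.0687), neuroectoderm 1 (0.0546) or 2 (0.0513) or mesendoderm 1 (0.0520) or 3 (0.0595), of 0.00236 to 0.114 over the alternatives. HOX genes rose in 4 of 5 cases, with HOXD1 the fall (call lost without hESC 1 or 2 or mesendoderm 1 (0.0548 to 0.0572); 4 and 1 adjusted over the list alone, list adjusted p = 0.092), led by HOXB6 (11.6, 1.57 and 7.51 RPKM in the mesendoderm libraries, 2.63 ± 0.47) and HOXB2 (1.94 ± 0.26). The list was called in 4 settings, without mesendoderm replicate 2 (0.00312), with small RNA left out (5.33e-06), with no filter (5.59e-04) and with a pseudocount of 0.1 (0.027), of 5.33e-06 to 0.177 over the alternatives.

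Epithelial and mesenchymal genes rose side by side. Of 15 epithelial genes 9 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.84), with the simple-epithelium keratins KRT8 (122 ± 24.6 to 919 ± 200.0 RPKM), KRT18 (2.07 ± 0.26) and KRT19 (2.50 ± 0.28), which have pseudogenes that can share reads, and claudin 4 (CLDN4, 2.86 ± 0.13). The epithelial list had adjusted p = 0.00116, and 0.221 with an estimated correlation. Of 13 mesenchymal genes 10 rose and 0 fell (11 and 0 adjusted over the list alone, median 1.61), including FN1, CDH11 (3.35 ± 0.44) and the proteoglycan lumican (LUM, 3.14 ± 0.31). The mesenchymal list had adjusted p = 1.43e-06, and 0.359 with an estimated correlation. Of 8 cardiac and smooth muscle genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), including cardiac actin (ACTC1, 3.08 ± 0.19) and MYL7 (2.84 ± 0.26). The cardiac and smooth muscle list had adjusted p = 0.0218, and 0.451 with an estimated correlation. With no filter it had 0.104, of 0.0033 to 0.104 over the alternatives. Of 5 endothelium and blood genes RUNX1 rose (1.02 ± 0.10) and TEK (-1.34 ± 0.11) and TIE1 (-0.76 ± 0.09) fell (1 and 2 adjusted over the list alone, list adjusted p = 0.401).

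NRF2 itself and part of its targets were higher in mesendoderm. NFE2L2 rose from 7.25 ± 0.626 to 12.3 ± 0.358 RPKM (0.70 ± 0.13, adjusted p = 0.00261) and NQO1 from 20.5 ± 1.99 to 38.7 ± 0.304 (0.89 ± 0.13, adjusted p = 7.51e-04). HMOX1 fell to 4.72 ± 0.453 (-0.94 ± 0.17, adjusted p = 0.00244) and KEAP1 did not pass the test (-0.02 ± 0.29, adjusted p = 0.971). Of 33 targets 8 rose and 3 fell (8 and 3 adjusted over the list alone, list adjusted p = 0.461). Rises included ferritin heavy chain (FTH1, 1.095 ± 0.32, adjusted p = 0.0278, call lost without hESC 2 or 3 or mesendoderm 2 or 3 (0.069 to 0.0954) and in 1 other setting), malic enzyme (ME1, 1.03 ± 0.10) and AKR1C1 (0.98 ± 0.14). The median was -0.10 and the mean 0.16, and over the scalings 8 to 12 rose and 3 to 8 fell. Among 11 regulators 2 rose, NFE2L2 and MAFF (0.44 ± 0.13, adjusted p = 0.0284, call lost without hESC 1, 2 or 3 or mesendoderm 1 or 3 (0.0596 to 0.107) and in 5 other settings), and 0 fell (2 and 0 adjusted over the list alone, list adjusted p = 0.561). Lysosome genes rose, 16 of 29 up and 1 down (18 and 1 adjusted over the list alone, median 0.63), with the cathepsins CTSB (1.43 ± 0.23) and CTSL (1.35 ± 0.15) and the proton pump subunit ATP6V1H (1.11 ± 0.10) up and TFE3 down (-1.01 ± 0.11). The lysosome list had adjusted p = 2.06e-05, and 0.470 with an estimated correlation. Of 43 autophagy genes 6 rose and 2 fell (5 and 0 adjusted over the list alone, list adjusted p = 0.223), WIPI1 (0.98 ± 0.17), GABARAPL1 (0.90 ± 0.18) and ULK2 (0.73 ± 0.15) among the rises. ULK1 (-0.03 ± 0.17, adjusted p = 0.917) and SQSTM1 (-0.22 ± 0.12, adjusted p = 0.194, past the threshold without the 3 libraries that stood apart (0.0283)) did not pass. Over the scalings 4 to 10 rose and 2 to 5 fell in the autophagy list. Of 33 proteasome genes PSMB5 rose (0.56 ± 0.15, adjusted p = 0.0181, call lost without hESC 1 or 2 or mesendoderm 1 or 3 (0.0506 to 0.0664) and in 3 other settings). PSMA5 fell (-0.45 ± 0.12, adjusted p = 0.0208, call lost without hESC 3 or mesendoderm 2 or 3 (0.0565 to 0.0828)). Adjusted over the list alone the counts were 0 and 0 (list adjusted p = 0.746), and over the scalings 0 to 8 rose and 1 to 6 fell.

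The cilium assembly list was not called in mesendoderm. Of 82 cilium assembly genes 15 fell and 7 rose (13 and 5 adjusted over the list alone, median -0.06, adjusted p = 0.378), with KIF17 (-1.102 ± 0.18), WDR35 (-1.08 ± 0.12) and BBS4 (-0.78 ± 0.11) lower and KIFAP3 higher (0.84 ± 0.18). Over the scalings 2 to 12 rose and 12 to 21 fell. IFT88 (-0.27 ± 0.18, adjusted p = 0.276, past the threshold without the 3 libraries that stood apart (0.0378)) and KIF3A (-0.20 ± 0.19, adjusted p = 0.459) did not pass the test. Of 13 disassembly genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, list adjusted p = 0.0568, called in 3 settings at 0.0141 to 0.0424), led by PIFO (2.82 ± 0.14) and NEDD9 (1.93 ± 0.13). Of 10 hedgehog genes 4 rose and 2 fell (4 and 2 adjusted over the list alone, list adjusted p = 0.378; GAS1 2.18 ± 0.21, GLI2 -1.42 ± 0.14). CDKN1A, the inhibitor p21, rose from 2.60 ± 0.177 to 26.8 ± 3.06 RPKM (2.94 ± 0.15). CCND1 (0.74 ± 0.16, adjusted p = 0.00612) and CCND2 (0.68 ± 0.16) rose too, and 4 of 14 G1 regulators rose and 1 fell (5 and 2 adjusted over the list alone, list adjusted p = 0.0934, called with no filter (0.0102)). Of 21 G1/S genes 6 fell and 2 rose (6 and 2 adjusted over the list alone, list adjusted p = 0.204), 10 falling without the 3 libraries that stood apart. Of 22 G2/M genes 2 fell and 1 rose (2 and 1 adjusted over the list alone, list adjusted p = 0.703; BUB1 -0.92 ± 0.13).

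Hypoxia response genes rose, 6 of 11 up and 0 down (6 and 0 adjusted over the list alone), with carbonic anhydrase 12 (CA12, 2.46 ± 0.16), NDRG1 (1.77 ± 0.14) and PDK1 (1.55 ± 0.14) higher. The hypoxia response list had adjusted p = 0.0236, and 0.483 with an estimated correlation. The call was lost with the GC correction (0.0542) and without the 3 libraries that stood apart (0.0673), of 0.00838 to 0.0673 over the alternatives. Of 18 glycolysis genes 5 rose and 1 fell (4 and 1 adjusted over the list alone, list adjusted p = 0.526), the glucose transporters SLC2A3 (46.4 ± 3.29 to 171 ± 13.5 RPKM) and SLC2A1 (1.21 ± 0.19) among the rises. None of 44 oxidative phosphorylation genes passed the limma test, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.209, called with no filter (0.0477) and without hESC 1 (0.0322)), whereas over the scalings 0 to 10 rose and 0 to 2 fell. In the unfolded protein and ATF4 list 4 of 15 rose and 2 fell (4 and 2 adjusted over the list alone, list adjusted p = 0.450), with the amino acid transporter SLC7A5 up (1.78 ± 0.18) and the serine synthesis gene PSAT1 down (-1.58 ± 0.17). Of 9 immediate early and heat shock genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, list adjusted p = 0.378), JUN (1.79 ± 0.26) among them. Of 32 histones 1 rose and 2 fell (0 and 2 adjusted over the list alone, list adjusted p = 0.461). With small RNA left out and the rest rescaled 1890 genes were higher and 3325 lower in mesendoderm, with a median of all genes of -0.164 in place of -0.017.

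The derived lineages were compared directly. At the preset correlation neural, ciliary and hedgehog lists were higher in neuroectoderm, and epithelial, streak, amnion, NRF2 target and lysosome lists in mesendoderm. With an estimated correlation the hedgehog, streak, amnion, NRF2 target and lysosome lists lost their calls. Of 14473 genes 3478 were higher and 3487 lower in neuroectoderm than in mesendoderm (48.1%), 998 and 1534 of them by at least 2-fold, and 57.2% did not overlap where chance gives 10%. The neuropeptide gene NTS differed most (0.160 ± 0.154 against 311 ± 44.6 RPKM, -8.07 ± 0.15, adjusted p = 4.28e-09), followed by PLA2G2A (-7.17 ± 0.11) and SERPINB9, an inhibitor of granzyme B (0.153 ± 0.031 against 164 ± 1.79 RPKM). CDH1 (-6.30 ± 0.12), BAMBI (-6.25 ± 0.18), HAND1 (-6.01 ± 0.23), FN1 (-5.98 ± 0.14), MIXL1 (-5.93 ± 0.25), CER1 (-5.85 ± 0.17) and the neuropeptide galanin (GAL, -5.82 ± 0.30) were also lower in neuroectoderm. Higher there were PAX3 (5.91 ± 0.18), the axonal adhesion molecule CNTN2 (44.7 ± 2.98 against 0.067 ± 0.031 RPKM), ZFHX4 (5.42 ± 0.07), NOS2 (5.40 ± 0.33), MAB21L2 (5.36 ± 0.11), the ephrin receptor EPHA7 (5.30 ± 0.14), PAPLN (5.12 ± 0.11), IGFBP5 (5.06 ± 0.16), the patterning factor IRX1 (5.03 ± 0.24) and GREB1L (4.96 ± 0.31).

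Of 30 neuroectoderm genes 28 were higher and 0 lower in neuroectoderm (28 and 0 adjusted over the list alone, median 2.63), with PAX6 (4.81 ± 0.17), NR2F1 (4.81 ± 0.21), the imprinted gene DLK1 (4.75 ± 0.22) and SOX1 (4.26 ± 0.16) among them. The neuroectoderm list had adjusted p = 2.47e-16, and 0.0409 with an estimated correlation. All 13 epithelial genes that passed of 15 were lower (13 and 0 adjusted over the list alone, median -3.87), including EPCAM (0.470 ± 0.139 against 69.1 ± 5.45 RPKM) and CLDN4 (-5.07 ± 0.13). The epithelial list had adjusted p = 1.45e-10, and 0.0409 with an estimated correlation. Lower as lists were primitive streak (19 of 20; T -4.74 ± 0.11), mesoderm (14 of 17; KDR -4.20 ± 0.11), amnion (12 of 13; GABRP -5.03 ± 0.20) and trophoblast (11 of 12; KRT7 -4.45 ± 0.16). The primitive streak list had adjusted p = 2.78e-09, and 0.0767 with an estimated correlation. The mesoderm list had adjusted p = 2.82e-06, and 0.467 with an estimated correlation. The amnion list had adjusted p = 1.11e-07, and 0.358 with an estimated correlation. The trophoblast list had adjusted p = 2.57e-07, and 0.0866 with an estimated correlation. Adjusted over the list alone the falls numbered 19, 15, 12 and 11. Pluripotency genes were lower too (18 down and 4 up of 26; 18 and 5 adjusted over the list alone), with NANOG (-3.47 ± 0.24) and NODAL (-5.30 ± 0.33) lower and SOX2 (3.52 ± 0.35) higher. The pluripotency list had adjusted p = 3.75e-04, and 0.657 with an estimated correlation. Mesenchymal genes were lower (8 down and 3 up of 13; 8 and 3 adjusted over the list alone; COL6A1 -3.56 ± 0.21), a call lost without mesendoderm replicate 1 (0.0630), without the 3 libraries that stood apart (0.0544) and with a replicate block on the 2 lineages alone (0.0769), of 0.00752 to 0.0769 over the alternatives. The mesenchymal list had adjusted p = 0.0387, and 0.750 with an estimated correlation.

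Cilium assembly was called between the lineages with the estimated correlation too, as were the neuroectoderm and epithelial lists. 54 of 82 genes were higher in neuroectoderm than in mesendoderm and 2 lower (56 and 3 adjusted over the list alone, median 0.61). The cilium assembly list had adjusted p = 3.10e-09, and 0.0409 with an estimated correlation. IFT81 (14.2 ± 1.80 against 3.71 ± 0.131 RPKM), DYNC2H1, the motor of retrograde ciliary transport (1.56 ± 0.16), IFT140 (1.40 ± 0.14) and the transition zone gene TMEM67 (1.24 ± 0.18) led. IFT88 (0.70 ± 0.18, adjusted p = 0.0101) and KIF3A (0.65 ± 0.19, adjusted p = 0.0189, call lost without mesendoderm 2 (0.069)) were higher as well. Of 13 disassembly genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone, list adjusted p = 0.577). Hedgehog genes were higher (7 up and 1 down of 10; 7 and 1 adjusted over the list alone), with BOC (3.33 ± 0.23), GLI3 (3.32 ± 0.12), CDON (2.07 ± 0.10) and GLI2 (1.73 ± 0.14). The hedgehog pathway list had adjusted p = 0.00879, and 0.672 with an estimated correlation.

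NRF2 targets were lower in neuroectoderm than in mesendoderm, 19 down and 4 up of 33 (19 and 4 adjusted over the list alone, median -0.73). The NRF2 target list had adjusted p = 0.00366, and 0.6 with an estimated correlation. NQO1 (-3.00 ± 0.13, adjusted p = 2.36e-07), EPHX1 (-2.46 ± 0.16), TKT (-2.10 ± 0.37) and GCLM, a subunit of the glutathione synthesis enzyme (-1.71 ± 0.13), were lower. So were NFE2L2 (-0.44 ± 0.13, adjusted p = 0.0187, call lost without mesendoderm 2 or 3 (0.0569 to 0.0576) and in 1 other setting) and HMOX1 (-0.49 ± 0.17, adjusted p = 0.0376, call lost without hESC 1 or neuroectoderm 1 or 2 or mesendoderm 1, 2 or 3 (0.055 to 0.114) and in 3 other settings). Regulators were mixed (3 up and 4 down of 11; 3 and 4 adjusted over the list alone, list adjusted p = 0.733). Lysosome genes were lower (18 down and 3 up of 29; 18 and 3 adjusted over the list alone), with the master regulator TFEB (-1.53 ± 0.17), NPC2 (-1.27 ± 0.24) and GLA (-1.13 ± 0.16). The lysosome list had adjusted p = 0.00137, and 0.703 with an estimated correlation. Autophagy genes were mixed (8 up and 9 down of 43; 7 and 9 adjusted over the list alone, list adjusted p = 0.912). SQSTM1 (-0.69 ± 0.12, adjusted p = 0.00137), GABARAPL1 (-1.59 ± 0.18) and WIPI1 (-1.57 ± 0.17) were lower and ATG16L2 (1.03 ± 0.22) and CALCOCO2 (0.93 ± 0.11) higher. ULK1 did not pass (-0.04 ± 0.17, adjusted p = 0.855). Over the scalings 5 to 12 higher and 7 to 12 lower genes were found. Proteasome genes were lower (16 down and 0 up of 33; 16 and 0 adjusted over the list alone), with POMP (-1.17 ± 0.14), PSMA3 (-1.16 ± 0.18) and PSMA6 (-1.12 ± 0.24), and 10 fell without mesendoderm replicate 2 or 3. The proteasome list had adjusted p = 2.60e-04, and 0.750 with an estimated correlation.

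**Figure D4:**
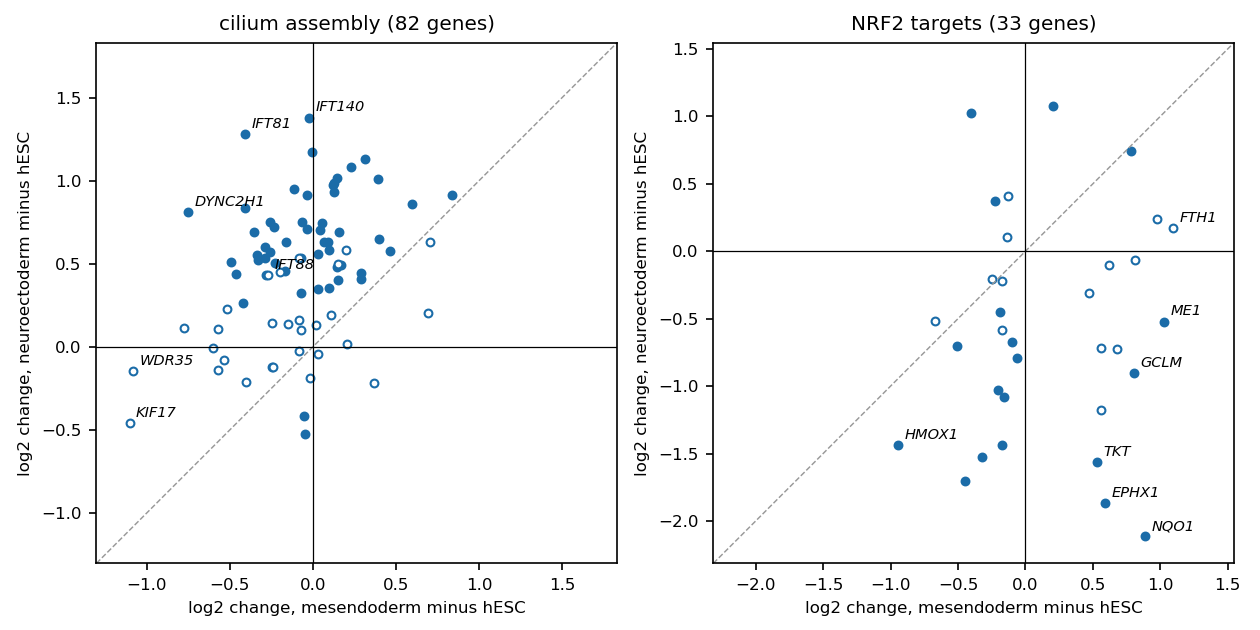
Log2 changes of cilium assembly genes (left) and NRF2 targets (right) against hESC, in neuroectoderm on the vertical axis and mesendoderm on the horizontal axis, with 1 point per gene, filled where the neuroectoderm change passed the test, and a dashed line of equal change. The medians are 0.51 and -0.06 for the cilium list and -0.59 and -0.10 for the NRF2 targets.

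Between the lineages, BMP targets (10 of 12 lower in neuroectoderm, 0 higher; 0 and 10 adjusted over the list alone) and Nodal targets (10 of 10 lower; 0 and 10 adjusted over the list alone) were lower in neuroectoderm. The BMP target list had adjusted p = 3.32e-05, and 0.358 with an estimated correlation. The Nodal and activin target list had adjusted p = 2.90e-07, and 0.358 with an estimated correlation. FGF and ERK targets were lower (6 down and 2 up of 10; 6 and 2 adjusted over the list alone), among them ETV4 (-4.29 ± 0.14) and SPRY4 (-3.72 ± 0.17), and the call was lost without the 3 libraries that stood apart (0.0544) and with a replicate block on the 2 lineages alone (0.0612), of 0.00527 to 0.0612 over the alternatives. The FGF and ERK target list had adjusted p = 0.0316, and 0.454 with an estimated correlation. WNT targets split, with APCDD1 (2.74 ± 0.23) and AXIN2 (2.39 ± 0.21) higher and RNF43 (-1.71 ± 0.10) and LGR5 (-1.64 ± 0.32) lower among 4 rises and 6 falls of 11 (4 and 6 adjusted over the list alone, list adjusted p = 0.642). Notch genes numbered 7 up and 4 down of 13 (8 and 4 adjusted over the list alone, list adjusted p = 0.160), with LFNG higher (3.30 ± 0.25). Retinoic acid genes numbered 1 up and 5 down of 7 (1 and 5 adjusted over the list alone, list adjusted p = 0.120, called without mesendoderm 2 (0.0482)), with DHRS3 lower (-3.78 ± 0.17). HOX genes numbered 0 up and 4 down of 5 (0 and 4 adjusted over the list alone, list adjusted p = 0.0895, called in 4 settings at 3.80e-04 to 0.0345), with HOXB6 lower (-2.66 ± 0.47). Neural crest and placode genes numbered 4 up and 7 down (4 and 7 adjusted over the list alone, list adjusted p = 0.291). Among them DLX5 was lower (-3.27 ± 0.10). Neuronal genes numbered 4 up and 4 down (4 and 4 adjusted over the list alone, list adjusted p = 0.843), with GAD1 lower (-3.67 ± 0.15). Endoderm genes numbered 1 up and 2 down (1 and 3 adjusted over the list alone, list adjusted p = 0.602), with CXCR4 higher (2.62 ± 0.27). Endothelium and blood genes numbered 2 up and 1 down (2 and 1 adjusted over the list alone, list adjusted p = 0.240), with TEK higher (2.07 ± 0.11). Cardiac and smooth muscle genes numbered 3 up and 2 down (3 and 2 adjusted over the list alone, list adjusted p = 0.698), with ACTA2 higher (3.54 ± 0.24).

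Glycolysis (12 down and 1 up of 18; 13 and 1 adjusted over the list alone, median -0.93) and oxidative phosphorylation genes (17 down and 0 up of 44; 13 and 0 adjusted over the list alone) were lower in neuroectoderm. They included ALDOC (-2.85 ± 0.15), PGK1 (-1.34 ± 0.19) and COX8A (-1.18 ± 0.29). In the latter list 27 fell without the 3 libraries that stood apart and 7 without mesendoderm replicate 2 or 3. The glycolysis list had adjusted p = 0.00118, and 0.750 with an estimated correlation. The oxidative phosphorylation list had adjusted p = 7.03e-04, and 0.778 with an estimated correlation. CDKN1A (-2.41 ± 0.15) and CCND2 (-1.04 ± 0.16) were lower and CDKN1B (1.05 ± 0.10) higher, while CCND1 did not pass (-0.41 ± 0.16, adjusted p = 0.0565, past the threshold in 8 settings at 0.00721 to 0.0485, among them the replicate block on the 2 lineages alone (0.0485)). The G1 regulators numbered 2 up and 3 down (2 and 3 adjusted over the list alone, list adjusted p = 0.779). G1/S genes numbered 2 up and 3 down (1 and 2 adjusted over the list alone, list adjusted p = 0.856), and G2/M genes 1 up and 3 down (1 and 1 adjusted over the list alone, list adjusted p = 0.9). Both balances turned with the scaling (1 to 6 higher and 2 to 4 lower, and 1 to 6 higher and 1 to 4 lower). Hypoxia genes numbered 3 up and 6 down (3 and 6 adjusted over the list alone, list adjusted p = 0.240), with PDK1 lower (-3.44 ± 0.14). Unfolded protein and ATF4 genes numbered 6 up and 5 down (6 and 5 adjusted over the list alone, list adjusted p = 0.733), with SLC7A5 lower (-2.93 ± 0.18). Immediate early genes numbered 2 up and 4 down (2 and 4 adjusted over the list alone, list adjusted p = 0.642), with ATF3 higher (2.04 ± 0.12). Ribosomal proteins (adjusted p = 0.0907, called in 5 settings at 0.00187 to 0.0358, among them the replicate block on the 2 lineages alone (0.00187), of 0.00187 to 0.539 over the alternatives that keep the preset correlation) and histones (adjusted p = 0.911) had no gene past the limma threshold, with 2 and 0 genes at an unadjusted p under 0.05. Over the scalings ribosomal proteins numbered 0 higher and 0 to 6 lower and histones 0 to 5 higher and 0 to 2 lower. Median, mean and test direction differed in sign, in lists that were not called, for endoderm, lysosome, retinoic acid, hypoxia and immediate early genes in neuroectoderm against hESC. The same held for neuronal genes, NRF2 targets and NRF2 regulators in mesendoderm against hESC, and for neuronal, G2/M, G1 regulator and histone genes between the lineages.

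Genes could change from hESC in both lineages. WLS, the WNT target SP5, the homeobox gene MSX1 (4.60 ± 0.43 in neuroectoderm and 4.29 ± 0.43 in mesendoderm), LEF1 and BMP4 rose in both, and IDO1, PRDM14, CHGA and LCK fell in both. In all 899 genes rose in both and 1233 fell in both, where independent lists of the same sizes would share 537 and 584. Another 382 rose in neuroectoderm and fell in mesendoderm and 501 the reverse, against 573 and 548 for independent lists. Unchanged groups simulated against the same hESC libraries gave 0 in each class. Without hESC replicate 3 the genes with opposite directions numbered 574 in place of 883. Log2 changes of the 2 lineages had a Pearson correlation across genes of 0.277, against 0.498 in simulated unchanged groups, and a covariance of 0.180 against 0.0234, a difference of 0.156. The 3 hESC libraries are too few to be split into parts of at least 2, so part of the excess over independent lists may come from the shared libraries.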

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

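The genes named here were chosen after their values were seen, except SMAD7, OTX2, COL6A1, KRT18, NQO1, CDH1 and PAX6. In 883 genes the lineages moved from hESC in opposite directions, fewer than independent lists would share. All also differed between the lineages, which follows from this. The inhibitory SMAD gene SMAD7 fell in neuroectoderm and rose in mesendoderm (-2.16 ± 0.12 and 1.63 ± 0.12), and OTX2 did the reverse (2.23 ± 0.11 and -2.32 ± 0.11). The MHC class II gene HLA-DQB1 was at 10.5 ± 2.58 RPKM in hESC, 2.77 ± 0.915 in neuroectoderm and 103 ± 10.2 in mesendoderm. The calcium-binding S100A11 (-2.71 and 1.74), the inflammasome adaptor PYCARD (-2.77 and 1.73), collagen VI (COL6A1, -1.73 and 1.83) and the keratin KRT18 (-1.75 and 2.07) fell in neuroectoderm and rose in mesendoderm, as did NQO1 (-2.11 and 0.89).

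At the preset correlation the neuroectoderm and epithelial lists were each called in opposite directions in the lineages. With an estimated correlation these calls against hESC were lost (adjusted p = 0.0971 and 0.470 for the neuroectoderm list, 0.0856 and 0.221 for the epithelial list). The neuroectoderm list in mesendoderm also lost its call with quantile normalization (0.0888) and without mesendoderm replicate 2 (0.0761). Members of the neuroectoderm list had a median difference between neuroectoderm and mesendoderm of 2.63, and members of the epithelial list one of -3.87. Both differences between the lineages passed the list test, also with an estimated correlation (adjusted p = 0.0409 for each). E-cadherin (CDH1) was at 54.7 ± 4.45 RPKM in hESC, 0.270 ± 0.121 in neuroectoderm and 98.8 ± 9.20 in mesendoderm, and PAX6 at 0.093 ± 0.021, 28.4 ± 7.2 and 0.023 ± 0.006.

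With 10 splits of 3 libraries against 3, the share as large as the real one is never under 0.1. On a comparison's 6 libraries, the real groups gave 5616, 6126 and 6219 changed genes for neuroectoderm and mesendoderm against hESC and neuroectoderm against mesendoderm. All other splits gave 0 (limma), but they mix cell types, whose difference then enters the spread. For called gene lists the real groups gave 16, 16 and 18 and the highest other splits 11, 22 and 17, with 1, 3 and 1 splits as large. The 22 lists came from setting hESC replicate 1 and mesendoderm replicates 1 and 3 against the rest. Neither test can thus judge the real groups.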

How the results depend on the processing

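The corrections for GC content and length, the fit without 3 libraries and the replicate block on the 2 lineages alone were chosen after the data were seen. No called result reversed its direction in the settings run. With estimated correlations, 0 lists were called in neuroectoderm or mesendoderm against hESC and 3 between them (camera in limma). The preset one gave 14, 16 and 18. The cilium assembly list in neuroectoderm against hESC then had adjusted p = 0.0856. The NRF2 target list had 0.808 there and 0.6003 against mesendoderm. Estimated correlations were 0.0272 and 0.145 for these lists, above the preset 0.01. With the preset correlation the cilium list stayed called, from 1.99e-08 to 8.37e-07 with 1 library left out and 1.50e-10 to 1.17e-06 in the other settings, and the NRF2 targets from 0.00748 to 0.0305 and 0.00492 to 0.0183. The autophagy list was not called in any setting, with 0.288 to 0.567 in neuroectoderm against hESC at the preset correlation and 0.964 with an estimated one. With 1 library left out, genes higher in neuroectoderm than hESC numbered 2468 to 4051 and lower 2550 to 3367, in mesendoderm against hESC 1827 to 3250 and 1813 to 3446, and in neuroectoderm against mesendoderm 2771 to 4104 and 2791 to 3485. Groups of 2 that remain take their spread from all libraries of the fit. A replicate block gave 2773 and 2870, 2100 and 2124, and 3096 and 3154. Residuals of libraries that share a replicate number correlated from -0.738 to 0.401, with 4 of 9 pairs above 0.1, and 1 of 9 libraries matched its own number best, so the numbers were not read as pairs across the 3 groups. Between neuroectoderm and mesendoderm alone the 3 pairs had 0.229 to 0.392, above 0.1 in each, so pairing of these lineages stays open. A replicate block on these 6 libraries gave 3242 higher and 3489 lower genes and 17 called lists, in place of 3478, 3487 and 18. With it the FGF and ERK target (0.0612) and mesenchymal (0.0769) lists lost their calls and ribosomal proteins gained one (0.00187).

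Genes changed in the same direction in both lineages numbered 3203 without hESC replicate 2, neuroectoderm replicate 1 and mesendoderm replicate 1, against 2132 with all libraries; the cause was not tested. A minimum of 2-fold in both lineages left 481 in the same and 118 in opposite directions, because fewer genes qualify. With 1 library left out the opposite genes ranged from 574 (without hESC replicate 3) to 1131 (without neuroectoderm replicate 1), and the cause was not tested. Of 476 results for genes that the naming rule selects 53 lost their call in at least 1 setting. Of the gene lists 5 lost their call in at least 1 fit with 1 library left out and 9 gained it, and 6 lost and 11 gained it in the other settings with the preset correlation. Over the scalings the balance of rises and falls among list members turned in 5 lists in neuroectoderm against hESC, 4 in mesendoderm against hESC and 4 between the lineages, of 38 each, and 0 of these lists were called. At this depth 3 reads on a transcript of 1 kb amount to 0.0425 to 0.0810 RPKM, which limits lineage genes near 0 in hESC.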

Other observations

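The tests on gene families, the genes named with them, the GC and length corrections and the test of small RNA reads were chosen after the data were seen. WNT ligands rose more often than other genes in both lineages. In neuroectoderm 10 of 14 tested WNT genes rose (one-sided Fisher's exact test, adjusted p = 0.00492, 0 fell), and 10 or 11 rose under each scaling. In mesendoderm 8 of 14 rose (adjusted p = 0.0279, 0 fell), and 8 under each scaling. Families omit genes with a mean under 0.5 RPKM, which can raise such shares. The ligands differed. WNT1 went from 0.093 ± 0.058 to 17.8 ± 8.16 RPKM in neuroectoderm and was at 0.033 ± 0.04 in mesendoderm. WNT2B (3.25), WNT7B (3.21) and WNT10B (3.16) also rose in neuroectoderm. WNT8A (4.11), WNT3 (3.78), WNT5A (3.52) and WNT6 (3.43) rose in mesendoderm, and WNT5B (3.25 and 4.68) and WNT4 (2.39 and 1.04) in both. The receptor FZD10 rose in both lineages (3.96 and 2.02) and FZD5 fell in both (-2.19 and -0.98).

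In mesendoderm all 10 tested keratin genes rose (adjusted p = 3.29e-06, median 2.003, 10 under each scaling), and 8 of 10 annexin genes (adjusted p = 0.00149, 7 to 9 under the scalings), ANXA1 by 4.53 ± 0.18 and ANXA2 by 3.35 ± 0.36. Keratins and annexins have pseudogenes or close relatives that share reads. The adhesion gene PCDH10 went from 0.967 ± 0.055 to 64.7 ± 5.55 RPKM, and B2M, the light chain of MHC class I, from 17.6 ± 1.17 to 58.1 ± 2.03. In neuroectoderm all 12 protocadherin gamma A genes rose (adjusted p = 2.37e-06, median 2.05, 12 under each scaling) and all 13 protocadherin alpha genes (adjusted p = 8.62e-07, median 0.58, 2 of 13 with small RNA left out), but the members share exons and their reads cannot be assigned to one gene. Zinc finger genes named ZNF were higher in neuroectoderm than in mesendoderm in 211 of 467 cases (adjusted p = 2.26e-21, 163 to 237 under the scalings). Of 11 HSPA chaperone genes 8 fell in neuroectoderm (adjusted p = 0.0209, 8 under each scaling), with HSPA8 at 679.8 ± 42.5 RPKM in hESC and 266 ± 5.66 in neuroectoderm. The small nucleolar RNA genes SNORD113-7 and SNORD113-9 of the DLK1 region rose in neuroectoderm by 5.16 ± 0.51 and 4.96 ± 0.50, with DLK1 itself at 0.547 ± 0.540 and 33.6 ± 4.71 RPKM. In 168 families 1008 tests were made, with Benjamini-Hochberg adjustment.

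A GC trend or neuroectoderm replicate 1 could have raised cilium assembly genes in neuroectoderm. Of 82 members 51 rose, 54 after the GC correction and 56 without that library. Rises of all genes grew too (3165, 3878 and 4051). The list stayed called, which argues against either as the whole cause. With small RNA left out 30 rose. A change of the ciliary programme with the lineage may underlie this rise, a hypothesis found and tested on the same data. Cilia and ciliated cells were not measured.

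Proteasome genes were lower in neuroectoderm than in hESC, with a median of -0.54. After the correction for GC content and length the median was -0.44, which argues against those trends as the whole cause. Without neuroectoderm replicate 1 the median was -0.34, between the bounds set for and against that library as the source, so a part played by this library stays possible and may explain some of the difference.

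Deviations of hESC replicate 2 and neuroectoderm replicate 1 from their groups had a correlation across genes of 0.787. After GC correction it was 0.732, which argues against GC as the whole cause. Leaving out small RNA (0.814) shifts genes nearly alike and cannot decide. Reads from DNA or unprocessed RNA could raise unexpressed genes. The mean of 49 olfactory receptor genes was 1.45 times the group's next highest in hESC replicate 2 and 2.39 times in neuroectoderm replicate 1. The bound set for this cause was 1.5 in both, so it stays open. The mesendoderm libraries had the highest means, 0.0994 to 0.128 RPKM.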
